A study of Mus musculus with 24 samples.

How the data were processed

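Per the labels, brains were digested enzymatically and cells were selected for CD11b with magnetic beads. Cells of neonatal MRL/lpr mice were cultured for 48 h in medium with 10% serum and then left unstimulated or exposed for 6 h to IFNg (interferon gamma), IL-6 (interleukin 6), IFNa (interferon alpha), TNFa (tumour necrosis factor alpha) or the mixture of these cytokines. Cytokine doses are not in the labels. MRL/lpr mice carry the lpr mutation of Fas and develop a lupus-like disease, and MRL/MpJ is the parent strain. Per the labels' protocols, total RNA was isolated with a column kit and libraries were made with a directional kit.

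Per the submitters' processing notes, cutadapt 2.1 and STAR 2.7.1a were used with the mm10 build. The deposited table gives raw read counts per gene, with no normalisation. Its length column gives gene length in bases, per the file headers. The counting program and its strand setting are not given in the sources used here, so reads of overlapping or antisense genes cannot be assigned with certainty. Counts of near-identical copies are uncertain for the same reason, among them Tgtp1 and Tgtp2, Hspa1a and Hspa1b, Gbp6 and Gbp10, Serpina3f and Serpina3g, Ccl2 and Ccl12, and the H2-Q genes. The table held 55434 genes, of which 28481 had at least 1 read and 99.41% matched GENCODE M21, which gave the mm10 coordinates. It held 0 genes of the mitochondrial genome, so mitochondrial reads were not analysed here. Total counts were 10.08 to 19.32 M (mega) per library, and 12.79 to 17.21 M in the adult libraries. The counts of the 24 pairs of same-group libraries all differed by more than counting error, with 5.36 the lowest chi-square per degree of freedom, and 0 pairs were identical.

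Counts were analysed in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM scaling, robust quasi-likelihood fit and F test). Benjamini-Hochberg adjustment was applied over all genes tested, and a gene was called at an adjusted p under 0.05. The 6 adult libraries (13799 genes tested, biological coefficient of variation 0.181, 4 residual degrees of freedom) and the 18 neonatal libraries (14626 genes, 0.397, 12 degrees of freedom) were fitted separately. Standard errors were the absolute log2 fold change divided by the square root of F. Levels are CPM (counts per M counts) as mean ± SD with n = 3 per group. They are scaled by TMM unless called plain CPM, which uses the library's total. Each cytokine and the mixture were compared with unstimulated cells, the mixture with each cytokine and with the sum of the 4 single log2 fold changes, and IFNg with IFNa. Where a group held 0 reads of a gene, the fold is a lower bound against a floor of 3 counts over the group, written as "at least". With 1 to 3 reads, the ratio has a 95% counting interval. Such intervals and floors cover counting error only.

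Before the data were examined, 15 function lists (334 genes) and 14 cell marker lists (152 genes) were fixed, together with the comparisons, the tests and the rule for named genes; 2 of the listed symbols were not in the table. Lists were tested with camera (limma 3.58.1) on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the 15 function lists or the 14 marker lists. Each test was repeated with an estimated correlation and with fry. The rule names Ikbke and Fas; up to 4 called members with the largest change from each list that was called or had at least 3 called members; and the 8 genes higher and 8 lower with the largest change among called genes with a mean log2 CPM of at least 2 and no overlap between groups, predicted genes skipped. It stops at 30 names per main comparison. The order of names within the lists was not fixed in advance, and the largest of every list was taken first, then the next. In the other comparisons the rule takes 5 genes each way. Genes named beyond the rule are said to be chosen after their values were seen.

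Replicate numbers are shared between groups, and whether they pair libraries was checked from the deviations of log2 CPM from the group means. All 45 pairs of same-numbered neonatal libraries had a correlation over 0.1 (0.184 to 0.687), so the numbers pair these libraries. The labels do not say what a number stands for. A fit with the replicate number as a block was run beside the fit without it. The adult numbers gave 3 pairs, of which 2 were over 0.1, and were not read as pairs.

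The steps were tested on simulated counts with 200 changed genes. In the simulated adult comparison (13439 genes), 75% of 2-fold and 94% of 4-fold changes were recovered, and 2.31% of the calls were false. In the simulated IFNg comparison (14235 genes), these were 53%, 85% and 3.5%. Alternatives were the replicate block, DESeq2 1.42.0, limma-voom, RLE size factors or total counts only in place of TMM, no filter or at least 1 CPM in 3 libraries, only the groups compared or all 24 libraries in 1 fit, and each replicate left out in turn. Scaling matters for the share of higher calls: with total counts only, the median log2 fold change of all genes moved to 0.27 in the adult comparison, -0.21 under IFNg and IFNa and -0.47 under the mixture. Changes are given relative to the TMM scale.

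In the neonatal libraries too few NK and erythroid markers were expressed for a test. Lists of nuclear-retained RNAs, glucocorticoid-induced genes and chemosensory receptors were chosen after results were seen. Mx1 and Cxcl11 are annotated as polymorphic pseudogenes.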

Results

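RNA-seq counts were compared in 24 libraries of CD11b-selected mouse brain microglia, 3 per group. The groups were cultured neonatal MRL/lpr microglia left unstimulated or exposed for 6 h to IFNg, IL-6, IFNa, TNFa or the mixture of all cytokines, and untreated microglia of 16-week-old MRL/lpr and MRL/MpJ mice. The series concerns Ikbke in the brain disease of lupus-prone mice. The gene (ENSMUSG00000042349, mm10 chromosome 1, 131254343 to 131279606, minus strand) encodes IKKepsilon, a kinase that with TBK1 acts upstream of type I interferon and of NF-kappaB signalling. Below, log2 fold changes are given ± SE, and "rose" or "fell" means an adjusted p under 0.05. Function list counts given once are the same adjusted over the list alone. Neonatal list counts are from the fit without the replicate block, so a 0 does not show absence of change. List members named without a value were chosen after their values were seen.

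Fas, the gene mutated by lpr (ENSMUSG00000024778, mm10 chromosome 19, 34290666 to 34327772, plus strand), was read first. Its plain CPM was 0.946 ± 0.714 (SD, n = 3) in adult MRL/lpr and 0.451 ± 0.243 in adult MRL/MpJ microglia. In the neonatal MRL/lpr cells it ran from 0.256 ± 0.284 with IFNa to 6.39 ± 2.57 with the mixture. Levels this low in both strains do not check the strain labels.

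**Figure D1:**
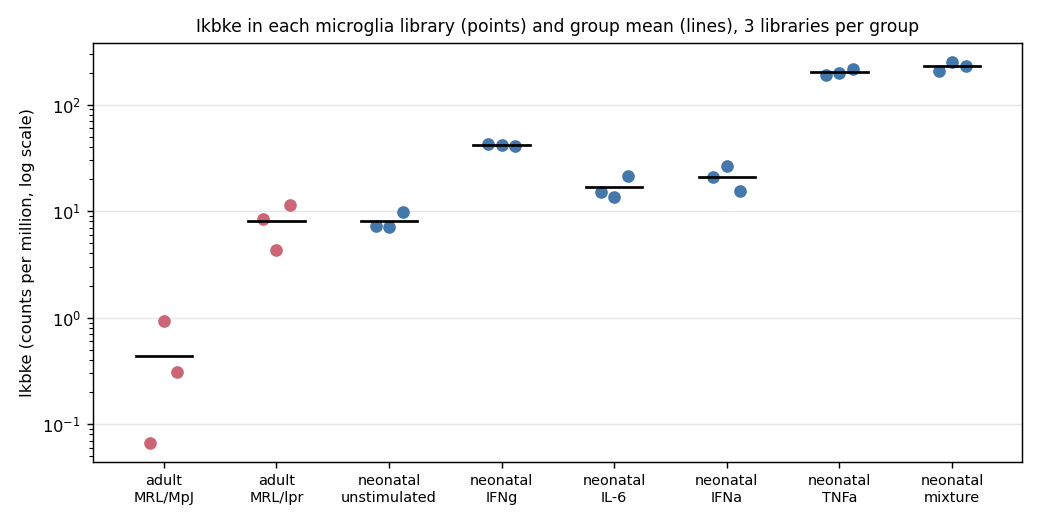
Plain CPM of Ikbke on a log axis in each of the 24 libraries, by group (points, 3 libraries each, with lines at the group means). The MRL/lpr adult libraries sit between 4.30 and 11.4 and the MRL/MpJ libraries between 0.067 and 0.938, and the TNFa and mixture groups lie highest.

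Adult MRL/lpr microglia were compared with MRL/MpJ microglia to ask how the cells differ in mice with lupus-like disease. Ikbke was 15.7-fold higher in MRL/lpr (log2 fold change 3.97 ± 0.634, edgeR adjusted p = 0.000364), at 7.33 ± 3.18 against 0.476 ± 0.483 CPM, with no overlap between the groups. The lists of type I interferon-stimulated genes, GTPases, chemokines and NK cell markers passed upwards. Those of homeostatic, disease-associated, complement and glycolytic genes and border macrophage markers passed downwards, though C3, Fcgr4, Pfkp, Pdk1 and Stab1 rose. Each of these lists lost its call with an estimated correlation (adjusted p = 0.296 to 0.632). Fas did not pass the test (0.79 ± 0.783, edgeR adjusted p = 0.438).

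Of the 30 type I interferon-stimulated genes, 15 rose and 0 fell (16 and 0 adjusted over the list alone), with a median log2 change of 0.79 (camera adjusted p = 0.000196 and 0.317 with an estimated correlation). The antiviral genes Oas2 (401 against 1 reads, ratio 293, 95% counting interval 52.3 to 11600) and Mx1 (5.12 ± 0.407) were the largest. Among 16 interferon-inducible GTPases 11 rose and 0 fell (median 1.21, camera adjusted p = 0.00142 and 0.322 with an estimated correlation). Gbp4 rose by 5.76 ± 0.569, and Gbp6 was at least 21.9-fold higher, with 0 reads in MRL/MpJ. Of 24 cytokine and chemokine genes, 17 rose and 1 (Ccl9) fell (18 and 1 adjusted over the list alone, median 1.45, camera adjusted p = 2.58e-05 and 0.302 with an estimated correlation). They included the T cell attractant Cxcl9 (4.91 ± 0.65) and the neutrophil attractant Cxcl2 (4.79 ± 0.729). The list of Ikbke's own pathway, the TBK1-IKKepsilon axis, held 12 higher and 5 lower genes of 22 (13 and 6 adjusted over the list alone, median 0.44) and did not pass its test (camera adjusted p = 0.0549). The nucleic acid sensor Zbp1 rose by 2.40 ± 0.343 in it.

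Of 20 homeostatic microglial genes, 0 rose and 15 fell (1 and 15 adjusted over the list alone, median -0.73, camera adjusted p = 2.58e-05 and 0.296 with an estimated correlation). The microglial marker Tmem119 fell 2.19-fold, from 7561 ± 285 CPM in MRL/MpJ to 3445 ± 279 in MRL/lpr (edgeR adjusted p = 5.11e-06), and the TGF-beta receptor Tgfbr1 fell 2.17-fold. Disease-associated microglial genes, induced around amyloid plaques in other models, fell in 12 and rose in 0 of 23 (median -0.54, camera adjusted p = 0.0024 and 0.328 with an estimated correlation). The growth factor Igf1 showed the largest fall (log2 fold change -1.62 ± 0.417). Complement and Fc receptor genes rose in 2 (C3 by 1.81 ± 0.361, and Fcgr4) and fell in 11 of 20 (2 and 12 adjusted over the list alone, median -0.33, camera adjusted p = 0.0163 and 0.322 with an estimated correlation). Glycolytic genes rose in 2 (Pfkp and Pdk1) and fell in 13 of 18 (median -0.46, camera adjusted p = 0.0024 and 0.296 with an estimated correlation), among them the glucose transporter Slc2a1 (-0.80 ± 0.148).

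Other function lists did not pass. NF-kappaB targets rose in 11 and fell in 5 of 28 (camera adjusted p = 0.168), with Nfkbiz 10.1-fold and Gadd45b 8.85-fold higher. STAT3 targets and IL-6 signalling rose in 4 and fell in 6 of 19 (median 0.07 with the test pointing down, camera adjusted p = 0.897), with the kinase genes Jak3 (1.78 ± 0.115) and Pim1 (1.26 ± 0.231) higher. MHC class I genes rose in 5 and fell in 3 of 18 (camera adjusted p = 0.673), with the transactivator Nlrc5 34.9-fold and H2-Q4 2.98-fold higher. MHC class II genes rose in 1 and fell in 1 of 12 (camera adjusted p = 0.289). Phagocytic receptors rose in 4 and fell in 9 of 22 (camera adjusted p = 0.192), and the scavenger receptor Marco was at least 86-fold higher, with 0 reads in MRL/MpJ. Cell cycle genes rose in 3 (Cenpe by 1.29 ± 0.473) and fell in 6 of 28 (2 and 6 adjusted over the list alone, camera adjusted p = 0.673).

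Signs of other cells and of RNA handling moved with the strain. NK cell markers rose in 7 and fell in 0 of 9 (8 and 0 adjusted over the list alone, median 2.61, camera adjusted p = 0.00176 and 0.344 with an estimated correlation), with Klre1 at 63 against 0 reads. T cell markers rose in 8 of 16 (camera adjusted p = 0.0693), with Cd8b1 at least 13.2-fold higher, monocyte markers in 5 of 10 (Itga4 1.78 ± 0.518; camera adjusted p = 0.286), and B or plasma cell markers in 3 of 7, with 1 lower (Igkc 3.22 ± 0.899; camera adjusted p = 0.383). Border macrophage markers fell in 8 and rose in 1 of 11 (1 and 10 adjusted over the list alone, median -1.37, camera adjusted p = 0.000966 and 0.632 with an estimated correlation), with Folr2 4.63-fold lower. Oligodendrocyte markers fell in 5 of 11 (7 adjusted over the list alone, median -0.90, camera adjusted p = 0.0264 and 0.667 with an estimated correlation), with Opalin 7.86-fold lower. Mural cell or fibroblast markers fell in 4 of 10 (5 adjusted over the list alone, median -0.97, camera adjusted p = 0.0378 and 0.344 with an estimated correlation), with Col1a2 4.59-fold lower. Neuron markers rose in 1 of 7, dendritic cell markers fell in 2 of 6, neutrophil markers fell in 1 of 13, and oligodendrocyte precursor markers changed in 0 of 5 (camera adjusted p = 0.383 for each of these lists). Astrocyte (10 genes, camera adjusted p = 0.774), endothelial cell (11 genes, camera adjusted p = 0.892) and erythroid markers (2 genes, camera adjusted p = 0.892) held 0 called genes.

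Dissociation-associated immediate early genes, which cell isolation can switch on, rose in 13 and fell in 1 of 18 (13 and 2 adjusted over the list alone, median 1.5, camera adjusted p = 7.34e-05 and 0.149 with an estimated correlation), with the heat shock gene Hspa1b 9.55-fold higher. Nuclear-retained RNAs were also higher in MRL/lpr: Malat1 at 1181 ± 216 against 114.5 ± 49 plain CPM, Neat1 at 72.7 ± 17 against 4.38 ± 1.29, and Xist at 1001 ± 281 against 61.0 ± 3.4. Ribosomal protein genes took 1.19 to 1.63% of reads in MRL/lpr and 2.08 to 2.46% in MRL/MpJ. Gm42418, which overlaps ribosomal RNA, stood at 1650 to 2165 plain CPM in MRL/lpr and at 3217, 11786 and 13375 in MRL/MpJ. These genes were chosen after their values were seen. These shifts go with the strain in all 6 libraries, and strain and preparation cannot be told apart, since the labels give no batch.

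In all, 6310 of 13799 genes (45.7%) passed the edgeR test, 3328 higher and 2982 lower in MRL/lpr, and 1882 and 406 of these changed at least 2-fold. With total counts in place of TMM, 4783 were higher and 1439 lower (76.9% against 52.7% higher). Without 1 library, 5 of the 29 called names lost their call: Cenpe (edgeR adjusted p = 0.168 without MRL/lpr replicate 1), Opalin (0.0782 without MRL/MpJ replicate 2), and Itga4 (0.112), Igkc (0.0901) and Hspa1b (0.0538) without MRL/MpJ replicate 3. Single libraries carried much of some changes: Opalin fell by 2.12 in log2 without MRL/MpJ replicate 2, and the rise was 2.34 for Hspa1b without MRL/lpr replicate 3, 2.23 for Igkc without MRL/lpr replicate 2 and 4.18 for Cxcl2 without MRL/MpJ replicate 3. The oligodendrocyte list lost its call without MRL/lpr replicate 1 (camera adjusted p = 0.0512) and the mural list without MRL/lpr replicate 2 (0.0575), while the TBK1-IKKepsilon axis passed without MRL/lpr replicate 1 (0.0454) or MRL/MpJ replicate 1 (0.0494) and with total counts (0.0438). The T cell list passed without MRL/lpr replicate 3 (0.0342) or any 1 MRL/MpJ library (0.0465 to 0.0487), the neutrophil list without MRL/MpJ replicate 1 (0.0485). Without MRL/lpr replicate 2 the MHC class II list passed downwards (0.00175) and the monocyte list upwards (0.0184). Replicate 2 held Cd74 at 1391 plain CPM against 581 and 562 in replicates 1 and 3.

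**Figure D2:**
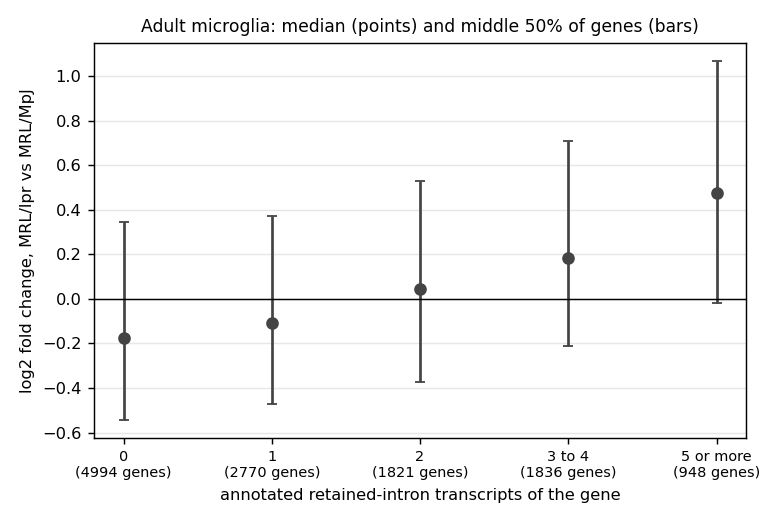
Log2 fold change of adult MRL/lpr against MRL/MpJ microglia (vertical axis) for genes grouped by their number of annotated retained-intron transcripts (horizontal axis), as the median (points) and the middle 50% of genes (bars). Medians go from -0.18 for genes with none to 0.48 for genes with 5 or more.

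IFNg, the type II interferon, was compared with unstimulated neonatal cells to ask how it acts on MRL/lpr microglia. Ikbke rose 5.79-fold (log2 fold change 2.54 ± 0.246, edgeR adjusted p = 5.16e-06), to 43.0 ± 1.32 from 7.39 ± 2.01 CPM. All 17 interferon-inducible GTPases rose, and the lists of NF-kappaB targets, chemokines and STAT3 targets passed upwards. Those of MHC class I, class II and complement genes passed too and lost the call with an estimated correlation (adjusted p = 0.0555 to 0.11). The change of Fas did not pass (1.40 ± 0.909, edgeR adjusted p = 0.416).

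The 17 GTPases had a median log2 change of 5.90 (camera adjusted p = 5.34e-31 and 0.0135 with an estimated correlation). Iigp1 rose by 10.83 ± 1.11, and Tgtp1 was at least 393-fold higher, with 0 reads in unstimulated cells. NF-kappaB targets rose in 24 of 29 (median 1.57, camera adjusted p = 2.21e-25), with the costimulatory receptor Cd40 at 6.98 ± 0.442 and the nitric oxide synthase Nos2 at least 40.6-fold higher. STAT3 targets rose in 11 of 20 (13 adjusted over the list alone, median 1.07, camera adjusted p = 3.24e-10), led by the feedback inhibitor Socs3 (5.38 ± 0.587) and Pim1 (3.50 ± 0.296). Cytokines and chemokines rose in 15 of 30 (17 adjusted over the list alone, median 2.49, or 1.56 with genes at 0 reads at their bound; camera adjusted p = 5.71e-11), led by Cxcl9 (11.69 ± 1.18) and Cxcl10 (8.73 ± 0.916). Dissociation-associated immediate early genes rose in 6 (8 adjusted over the list alone) and fell in 2 of 18 (camera adjusted p = 0.0014), with Zfp36 at 1.5 ± 0.179 and Nr4a1 at -1.97 ± 0.488. These lists kept their call with an estimated correlation (0.00252 to 0.0136).

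The other called lists lost theirs with an estimated correlation, which gives the second p of each list. Type I interferon-stimulated genes rose in 11 of 30 (19 adjusted over the list alone, median 1.16, camera adjusted p = 7.21e-11 and 0.194), with Isg20 at 2.38 ± 0.606 and Parp14 at 2.13 ± 0.248. MHC class I genes rose in 10 of 18 (12 adjusted over the list alone, median 0.89, camera adjusted p = 8.16e-10 and 0.11), with Nlrc5 at 4.2 ± 0.525 and the peptide transporter Tap1 at 2.96 ± 0.384. MHC class II genes rose in 4 of 12, Ciita, Cd74, H2-DMa and H2-Oa (median 0.70, camera adjusted p = 0.0014 and 0.0555). Ciita, the class II transactivator, had 682 against 3 reads (ratio 243, 95% counting interval 82.8 to 1180). Complement and Fc receptor genes rose in 9 of 21 (10 adjusted over the list alone, median 0.76, camera adjusted p = 7.21e-07 and 0.0701), with Serping1 at 4.0 ± 0.632 and Fcgr4 at 3.09 ± 0.508. The TBK1-IKKepsilon axis rose in 12 and fell in 2 of 22 (median 0.71, camera adjusted p = 6.43e-07 and 0.0564), with Zbp1 at 2.90 ± 0.454 and Tmem173, which encodes STING, at 2.88 ± 0.328.

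Cell cycle genes fell in 3 of 28 under IFNg (median -0.41, camera adjusted p = 7.56e-05 and 0.194 with an estimated correlation), with E2f1 at -0.86 ± 0.186. Glycolytic genes rose in 4 of 18 (with Pfkp at 1.75 ± 0.256 and Hk2 at 1.41 ± 0.225, median 0.06, camera adjusted p = 0.0325 and 0.194 with an estimated correlation). Homeostatic genes went both ways, 3 higher (P2ry12, P2ry13 and Sall1) and 7 lower of 20 (camera adjusted p = 0.0738), with the fractalkine receptor Cx3cr1 6.85-fold and Gpr34 5.37-fold lower. Phagocytic receptors rose in 3 (Pros1, Timd4 at 4.12 ± 0.716 and Cd300lf at 1.55 ± 0.202) and fell in 2 of 23 (4 and 4 adjusted over the list alone, camera adjusted p = 0.619), and disease-associated genes rose in 2 of 24 (camera adjusted p = 0.952). None of the cell marker lists passed (camera adjusted p from 0.256 to 0.833), except that of neutrophils without unstimulated replicate 3 (0.00441).

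Under IFNg, 1886 genes passed the edgeR test (12.9% of 14626), 1254 higher and 632 lower. With the replicate number as a block they were 3468, 2156 higher and 1312 lower, and with total counts in place of TMM 996 were higher and 1211 lower. Without 1 library, Isg20 (edgeR adjusted p = 0.0881) and Nr4a1 (0.0644, both without IFNg replicate 3) and H2-Oa (0.0701 without IFNg replicate 2) lost their call, and the count fell to 1240 without IFNg replicate 2 and the lower count to 368 without unstimulated replicate 2. The glycolytic list lost its call with total counts (camera adjusted p = 0.249), without unstimulated replicate 1 (0.0881) and without IFNg replicate 2 (0.0697). The homeostatic list passed without unstimulated replicate 1 (0.0107) or IFNg replicate 3 (0.0236), and Cxcl9 and Nos2 lost theirs with limma-voom (adjusted p = 0.0696 and 0.138).

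IL-6, a cytokine that signals through STAT3, changed fewer genes than the other cytokines, and STAT3 targets led its response. Socs3 rose 52.3-fold (5.71 ± 0.595, edgeR adjusted p = 0.000213), the IL-4 receptor chain Il4ra 8.97-fold and Stat3 itself 3.00-fold. Ikbke was 2.11-fold higher (1.08 ± 0.241, edgeR adjusted p = 0.0432), at 15.6 ± 4.57 CPM. This call ended with limma-voom (adjusted p = 0.114), with only the groups compared (0.203), and without any of 5 of the 6 libraries (up to 0.245 without unstimulated replicate 2). The change of Fas did not pass (log2 fold change -0.88 ± 0.94, edgeR adjusted p = 0.884).

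STAT3 targets rose in 6 of 20 (11 adjusted over the list alone, median 0.86, camera adjusted p = 1.29e-13 and 0.000507 with an estimated correlation), with Cebpb at 1.01 ± 0.168. All other calls were lost with an estimated correlation, which gives the second p of each list. Interferon-inducible GTPases rose in 3 of 17 (4 adjusted over the list alone, median 0.93, camera adjusted p = 3.86e-06 and 0.326), Gbp2 (2.37 ± 0.438), Gbp7 (2.23 ± 0.501) and Gbp3 (2.08 ± 0.303). Cytokines and chemokines rose in 3 of 30 (9 higher and 1 lower adjusted over the list alone, median 0.39, camera adjusted p = 0.000147 and 0.325), the monocyte attractants Ccl12 (4.04 ± 0.574) and Ccl2 (1.86 ± 0.38) and Cxcl16 (1.03 ± 0.172). NF-kappaB targets rose in 1 of 29, Bcl3 (2.29 ± 0.178, with 4 adjusted over the list alone, median 0.25, camera adjusted p = 0.000157 and 0.325). Complement and Fc receptor genes rose in 2 of 21, Fcgr2b (1.66 ± 0.374) and Fcgr3 (0.89 ± 0.201, with 6 adjusted over the list alone, median 0.37, camera adjusted p = 5.58e-05 and 0.325). The TBK1-IKKepsilon axis rose in 2 of 22, Tmem173 (1.70 ± 0.315) and Ikbke (3 adjusted over the list alone, median 0.11, camera adjusted p = 0.0348 and 0.501, or 0.0623 with the replicate block).

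Type I interferon-stimulated genes changed in 0 of 30 with IL-6, and in 0 adjusted over the list alone (median 0.04, camera adjusted p = 0.962). MHC class I genes changed in 0 of 18 (median 0.26, camera adjusted p = 0.00623 and 0.596 with an estimated correlation) and cell cycle genes in 0 of 28, with 1 lower adjusted over the list alone (median -0.36, camera adjusted p = 0.000102 and 0.326 with an estimated correlation). MHC class II genes changed in 0 of 12 (camera adjusted p = 0.899), the homeostatic list of 20 genes did not pass (0.805), and disease-associated genes rose in 1 of 24 (0.925). Immediate early genes rose in 1 of 18, Zfp36 (2 adjusted over the list alone, camera adjusted p = 0.165), phagocytic receptors fell in 1 of 23 (0.199), and glycolytic genes changed in 0 of 18, with 1 higher adjusted over the list alone (0.805). Of the marker lists, that of neurons passed (median 1.45, camera adjusted p = 0.00744 and 0.971 with an estimated correlation), with 1 of 11 genes called, the neurofilament gene Nefm (5.36 ± 1.19). The other marker lists did not pass (camera adjusted p from 0.185 to 0.988). Without IL-6 replicate 1 the T cell (0.0252), neutrophil (0.0394), border macrophage (0.0387) and mural lists (0.0176) passed. So did the T cell (0.0122), border macrophage (0.0227) and mural lists (0.0122) without unstimulated replicate 2, and the T cell and neutrophil lists (0.03 for both) without unstimulated replicate 3. The astrocyte (0.0132) and phagocytic lists (0.0191) passed without unstimulated replicate 1. Further genes raised by IL-6 were the matrix gene Tgfbi (3.04 ± 0.371), Zdhhc23 (2.98 ± 0.615), the chemokine receptor Ccr1 (2.96 ± 0.207), Cd38 (2.59 ± 0.343), Gcnt2 (2.54 ± 0.333) and Arid5a (2.48 ± 0.35). The largest falls were in Cd28 (-1.95 ± 0.377), C77080 (-1.57 ± 0.22), Acot1 (-1.55 ± 0.323), Rasgrp3 (-1.53 ± 0.173), Slc46a3 (-1.39 ± 0.204), N4bp2l1 (-1.33 ± 0.277) and Ccng2 (-1.32 ± 0.197).

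IL-6 changed 143 genes in the edgeR test, 109 higher and 34 lower, and 714 with the replicate block, 444 higher and 270 lower. Any single library left out lowered the count, to between 53 and 94. Of 29 called names, 16 kept their call without any 1 library. The highest edgeR adjusted p of the others was 0.279 for Gbp7, 0.244 for Nefm, 0.184 for Ccl2, 0.183 for Zdhhc23, 0.117 for Gbp2, 0.108 for Tmem173 and 0.0567 for Cxcl16, each without unstimulated replicate 2. It was 0.217 for Fcgr2b without unstimulated replicate 3, 0.206 for Fcgr3 without unstimulated replicate 1, 0.103 for Cd28 without IL-6 replicate 1, and 0.146 for N4bp2l1 and 0.144 for Acot1 without IL-6 replicate 2. The MHC class I list lost its call without unstimulated replicate 1 (camera adjusted p = 0.359) or IL-6 replicate 3 (0.55), the TBK1-IKKepsilon axis without unstimulated replicate 1 (0.359) or IL-6 replicate 2 (0.104) or 3 (0.157), and the neuron list without IL-6 replicate 2 (0.165). The type I interferon list passed upwards without IL-6 replicate 1 (0.0265) or unstimulated replicate 3 (0.00135) and downwards without IL-6 replicate 3 (0.0114). Nefm lost its call with limma-voom (adjusted p = 0.586), as did Ccl12 (0.192) and Gbp7 (0.0567). With only the groups compared Gbp2 (edgeR adjusted p = 0.116), Gbp7 (0.144), Gbp3 (0.0773), Cebpb (0.0505), Nefm (0.191), Ccl2 (0.144) and N4bp2l1 (0.0708) lost it.

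IFNa, a type I interferon, raised most of the interferon-stimulated genes and all GTPases, and raised Ikbke 2.90-fold (1.53 ± 0.241, edgeR adjusted p = 0.00036), to 21.5 ± 5.94 CPM. Type I interferon-stimulated genes rose in 25 of 30 (median 2.42, camera adjusted p = 9.16e-26 and 0.0644 with an estimated correlation). Cmpk2 (5.76 ± 0.882), the antiviral enzyme gene Rsad2 (5.56 ± 0.969) and Isg20 (4.33 ± 0.652) led them. At the same time Fas did not pass (log2 fold change -1.46 ± 0.977, edgeR adjusted p = 0.423).

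With IFNa the 17 GTPases all rose (median 5.01, camera adjusted p = 2.38e-25), among them Iigp1 (8.56 ± 1.04), Gbp5 (6.76 ± 0.584) and Tgtp1 (at least 168-fold higher). Cytokines and chemokines rose in 19 of 30 (median 2.76, camera adjusted p = 6.47e-15), led by Cxcl10 (8.44 ± 0.906) and Cxcl9 (8.13 ± 1.14). NF-kappaB targets rose in 18 and fell in 1 of 29 (20 and 1 adjusted over the list alone, median 1.04, camera adjusted p = 6.65e-12), with Cd40 at 5.96 ± 0.432 and Nos2 at least 37.6-fold higher. The TBK1-IKKepsilon axis rose in 14 of 22 (14 higher and 2 lower adjusted over the list alone, median 0.86, camera adjusted p = 2.94e-08), with the double-stranded RNA receptor Tlr3 at 3.63 ± 0.471 and Zbp1 at 3.35 ± 0.462. STAT3 targets rose in 8 of 20 (median 0.61, camera adjusted p = 6.94e-05), with Pim1 at 2.18 ± 0.281 and Stat3 at 1.41 ± 0.153. Immediate early genes rose in 8 (11 adjusted over the list alone) and fell in 1 of 18 (camera adjusted p = 2.54e-05), with Hspa1b at 2.79 ± 0.883 and Egr2 at -2.02 ± 0.603. These lists kept their call with an estimated correlation (0.00722 to 0.0387).

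MHC class I genes rose in 9 of 18 with IFNa (12 adjusted over the list alone, median 1.08, camera adjusted p = 4.59e-10 and 0.116 with an estimated correlation), with Nlrc5 at 4.17 ± 0.524 and Tap1 at 2.92 ± 0.384, and MHC class II genes in 1 of 12 (H2-Oa; camera adjusted p = 0.67). Complement and Fc receptor genes rose in 6 of 21 (7 adjusted over the list alone, median 0.22, camera adjusted p = 0.0386 and 0.469 with an estimated correlation), with Serping1 at 2.40 ± 0.612 and Fcgr4 at 2.1 ± 0.489. Cell cycle genes rose in 1 (Mcm6, 0.91 ± 0.168) and fell in 3 of 28 (median -0.40, camera adjusted p = 0.00673 and 0.469 with an estimated correlation), with E2f1 at -0.71 ± 0.185. Homeostatic genes rose in 3 and fell in 6 of 20 (camera adjusted p = 0.095), with Gpr34 5.17-fold and Cx3cr1 3.07-fold lower. Phagocytic receptors rose in 2 (Timd4 3.50 ± 0.707 and Cd300lf 2.28 ± 0.206) and fell in 4 of 23 (2 and 5 adjusted over the list alone, median -0.37, camera adjusted p = 0.0712, and 0.0247 with the replicate block). Glycolytic genes rose in 4 (Pfkfb3 at 1.55 ± 0.173, Pfkp at 0.94 ± 0.251) and fell in 1 of 18 (camera adjusted p = 0.67), and disease-associated genes changed in 0 of 24 (camera adjusted p = 0.289). No marker list passed (camera adjusted p from 0.588 to 0.971), except that of neutrophils without unstimulated replicate 3 (0.0411), and the disease-associated list passed without unstimulated replicate 1 (0.0448).

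IFNa changed 2118 genes in the edgeR test, 1377 higher and 741 lower, and without 1 library 1014 to 1259 and 401 to 740. Cxcl9 rose by 7.51 without IFNa replicate 2. With the replicate block they were 3712, 2093 higher and 1619 lower, and with total counts in place of TMM 1190 were higher and 1560 lower. Without 1 library, Egr2 (edgeR adjusted p = 0.122) and E2f1 (0.0902) without IFNa replicate 1, Hspa1b (0.0925) without IFNa replicate 3, and Pfkp (0.0982) and Serping1 (0.0753) without unstimulated replicate 2 lost their call. The complement list lost its call with total counts (camera adjusted p = 0.0534) and without unstimulated replicate 1 (0.0882) or 2 (0.0629) or IFNa replicate 2 (0.0798) or 3 (0.0568). The homeostatic and phagocytic lists passed without unstimulated replicate 1 (0.0187 and 0.0173) or IFNa replicate 3 (0.0269 and 0.0214), and with limma-voom Cxcl9 (adjusted p = 0.231), Nos2 (0.11), Serping1 (0.292), Timd4 (0.0749) and Egr2 (0.151) lost their call.

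TNFa, an activator of NF-kappaB, raised Ikbke 25.9-fold (4.70 ± 0.266, edgeR adjusted p = 1.78e-08), to 192 ± 29.4 CPM. NF-kappaB targets rose in 21 of 29 (25 adjusted over the list alone, median 2.19, camera adjusted p = 2.03e-43), led by the signalling adaptor Traf1 (7.49 ± 0.609) and Cd40 (5.82 ± 0.43). Cytokines and chemokines rose in 15 of 30 (22 higher and 1 lower adjusted over the list alone, median 2.19, camera adjusted p = 3.68e-17), with Cxcl10 at 6.8 ± 0.854, Cxcl3 at 5.94 ± 1.44 and Il1b at 5.87 ± 0.735. STAT3 targets rose in 8 and fell in 1 of 20 (9 and 2 adjusted over the list alone, median 0.64, camera adjusted p = 9.8e-07), with Socs3 at 3.67 ± 0.552, Pim1 at 2.56 ± 0.285 and Cebpb at 2.16 ± 0.173. These lists kept their call with an estimated correlation (0.000409 to 0.00565). Fas did not pass (1.73 ± 0.911, edgeR adjusted p = 0.343) and passed with the replicate block (0.0467).

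All other TNFa calls were lost with an estimated correlation, which gives the second p of each list. Homeostatic genes rose in 1, Tmem119, and fell in 7 of 20 (1 and 9 adjusted over the list alone, median -0.46, camera adjusted p = 0.00154 and 0.29), with Gpr34 4.75-fold and P2ry13 3.88-fold lower. Phagocytic receptors rose in 1, Marco (3.02 ± 0.498), and fell in 7 of 23 (2 and 7 adjusted over the list alone, median -0.32, camera adjusted p = 0.00134 and 0.29), with Cd300lf at -1.39 ± 0.203. The TBK1-IKKepsilon axis rose in 4 of 22, with Tank (2.00 ± 0.201) and Sqstm1 (1.47 ± 0.227, list median 0.38, camera adjusted p = 2.67e-05 and 0.182). Interferon-inducible GTPases rose in 5 of 17 (8 adjusted over the list alone, median 1.65, camera adjusted p = 7.53e-07 and 0.29), with Gbp5 at 4.07 ± 0.527, Gbp2 at 3.03 ± 0.448 and Gbp7 at 2.41 ± 0.503. Of the type I interferon-stimulated genes, 2 of 30 rose, Ifit1 (1.93 ± 0.557) and Parp14 (1.33 ± 0.242, with 1 adjusted over the list alone, median 0.59, camera adjusted p = 0.000751 and 0.531). MHC class I genes rose in 1 of 18, Psme2 (0.82 ± 0.175, list median 0.26, camera adjusted p = 0.0132 and 0.531). Complement and Fc receptor genes rose in 3, C1qa, C3 (3.20 ± 0.276) and C5ar1 (1.99 ± 0.496), and fell in 1 of 21 (median 0.18, camera adjusted p = 0.0356 and 0.531).

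Cell cycle genes fell in 4 of 28 with TNFa (median -0.28, camera adjusted p = 0.00374 and 0.521 with an estimated correlation), with Pcna at -0.81 ± 0.135 and Mcm2 at -0.75 ± 0.182. MHC class II genes rose in 2 of 12 (camera adjusted p = 0.358), disease-associated genes rose in 1 and fell in 1 of 24 (0.384), and glycolytic genes rose in 2 of 18 (0.509). Immediate early genes rose in 4 (Fos at 1.91 ± 0.246 among them) and fell in 2 of 18 (Atf3 at -1.32 ± 0.182, 4 and 4 adjusted over the list alone, camera adjusted p = 0.636), and Nos2 was at least 18.6-fold higher. No marker list passed (camera adjusted p from 0.573 to 0.984).

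TNFa changed 1184 genes in the edgeR test, 640 higher and 544 lower, and 2542 with the replicate block, 1313 higher and 1229 lower. With total counts 638 were higher and 764 lower, and without unstimulated replicate 2 the lower count was 337. Without 1 library, Ifit1 (1.02, edgeR adjusted p = 0.337) and Nos2 (0.16) without TNFa replicate 3, Mcm2 (0.092) without TNFa replicate 2, and C5ar1 (0.0958) and Cxcl3 (0.0803) without unstimulated replicate 2 lost their call. Cxcl10 rose by 5.66 and Gbp7 by 1.65 without TNFa replicate 3. Without that library the type I interferon (camera adjusted p = 0.465), MHC class I (0.302) and complement lists (0.271) lost theirs, and without unstimulated replicate 1 so did these lists (0.0838, 0.264 and 0.139) and that of the cell cycle (0.0793). The complement list also lost it without unstimulated replicate 2 (0.069) or TNFa replicate 2 (0.0761), and Nos2 lost its call with limma-voom (adjusted p = 0.303).

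The mixture of all cytokines gave the largest response. Ikbke rose 37.5-fold (5.23 ± 0.272, edgeR adjusted p = 3.99e-09), to 278 ± 42.6 CPM, and all 29 NF-kappaB targets and all 17 GTPases rose. Interferon-stimulated genes rose in 27 of 30 and cytokines and chemokines in 26 of 30. Cell cycle genes fell in 13 of 28. Fas, at 0.716 ± 0.556 CPM unstimulated, rose to 7.61 ± 2.62 (3.40 ± 0.959, edgeR adjusted p = 0.0117), a call that ended without unstimulated replicate 2 (0.0505).

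NF-kappaB targets had a median log2 change of 2.78 with the mixture (camera adjusted p = 4.68e-27), with Cd40 at 9.76 ± 0.478 and Nos2 at least 2390-fold higher. Cytokines and chemokines had a median of 4.83, or 4.51 with genes at 0 reads at their bound (27 higher adjusted over the list alone, camera adjusted p = 1.99e-19), led by Cxcl9 (13.68 ± 1.23) and Cxcl11 (11.49 ± 1.2). The GTPases had a median of 5.93 (camera adjusted p = 1.4e-18), with Iigp1 at 10.51 ± 1.1 and Tgtp1 at least 1170-fold higher. STAT3 targets rose in 12 and fell in 2 of 20 (12 and 3 adjusted over the list alone, median 1.78, camera adjusted p = 4.87e-07), with Socs3 at 4.87 ± 0.576 and Pim1 at 4.51 ± 0.309. The TBK1-IKKepsilon axis rose in 14 and fell in 2 of 22 (15 and 2 adjusted over the list alone, median 1.34, camera adjusted p = 1.13e-07), with Tlr3 at 3.90 ± 0.477. Immediate early genes rose in 10 and fell in 1 of 18 (11 and 1 adjusted over the list alone, camera adjusted p = 0.000101), with Hspa1b at 2.56 ± 0.877. These lists kept their call with an estimated correlation (0.00227 to 0.048).

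Type I interferon-stimulated genes had a median of 2.64 with the mixture (28 higher adjusted over the list alone, camera adjusted p = 1.44e-18 and 0.106 with an estimated correlation), led by Rsad2 (6.46 ± 1.01) and Cmpk2 (6.4 ± 0.909). MHC class I genes rose in 14 of 18 (15 adjusted over the list alone, median 1.63, camera adjusted p = 4.93e-10 and 0.106 with an estimated correlation), with Nlrc5 at 4.83 ± 0.54 and Tap1 at 3.87 ± 0.4. Complement and Fc receptor genes rose in 14 of 21 (15 adjusted over the list alone, median 0.97, camera adjusted p = 8.22e-07 and 0.0818 with an estimated correlation), with Serping1 at 5.38 ± 0.662 and C3 at 5.06 ± 0.298. The cell cycle list had a median of -0.81 (13 lower adjusted over the list alone, camera adjusted p = 5.91e-05 and 0.225 with an estimated correlation), with Kif20a at -1.49 ± 0.459.

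Lists that did not pass with the mixture still held called genes. MHC class II genes rose in 4 of 12, Ciita, Cd74, H2-DMa and H2-Oa (5.63 ± 0.817, camera adjusted p = 0.0817), and Ciita had a read ratio of 62.3 (95% counting interval 20.9 to 306). Homeostatic genes rose in 3 and fell in 8 of 20 (camera adjusted p = 0.0739), with Gpr34 7.86-fold and Tmem119 7.76-fold lower. The homeostatic list passed without unstimulated replicate 1 (camera adjusted p = 0.0183) or mixture replicate 3 (0.0135). Disease-associated genes rose in 4, among them Cst7 (6.15 ± 0.624) and Csf1 (1.84 ± 0.57), and fell in 1 of 24 (3 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.703). Phagocytic receptors rose in 5, among them Timd4 (6.16 ± 0.764) and Cd300lf (1.85 ± 0.204), and fell in 7 of 23 (5 and 8 adjusted over the list alone, camera adjusted p = 0.379). Glycolytic genes rose in 4, among them Pfkp (2.13 ± 0.259), and fell in 3 of 18 (4 and 4 adjusted over the list alone, camera adjusted p = 0.326). No marker list passed (camera adjusted p from 0.115 to 0.981), with Ms4a4c at 4.09 ± 1.22 and the oligodendrocyte marker Cnp, an interferon-inducible gene, at 2.53 ± 0.246.

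The mixture changed 4687 genes in the edgeR test (32% of 14626), 2289 higher and 2398 lower. With total counts in place of TMM, 1547 were higher and 4993 lower. Without 1 library, Hspa1b (1.88, edgeR adjusted p = 0.167) without mixture replicate 3, Kif20a (0.128) without unstimulated replicate 1, Csf1 (0.104) without mixture replicate 1 and Ms4a4c (0.0783) without unstimulated replicate 2 lost their call. Hspa1b and Csf1 lost it with total counts (edgeR adjusted p = 0.0719 and 0.0926) and Ciita with limma-voom (adjusted p = 0.112), and the monocyte and dendritic cell lists passed with total counts (camera adjusted p = 0.0296 for both).

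**Figure D3:**
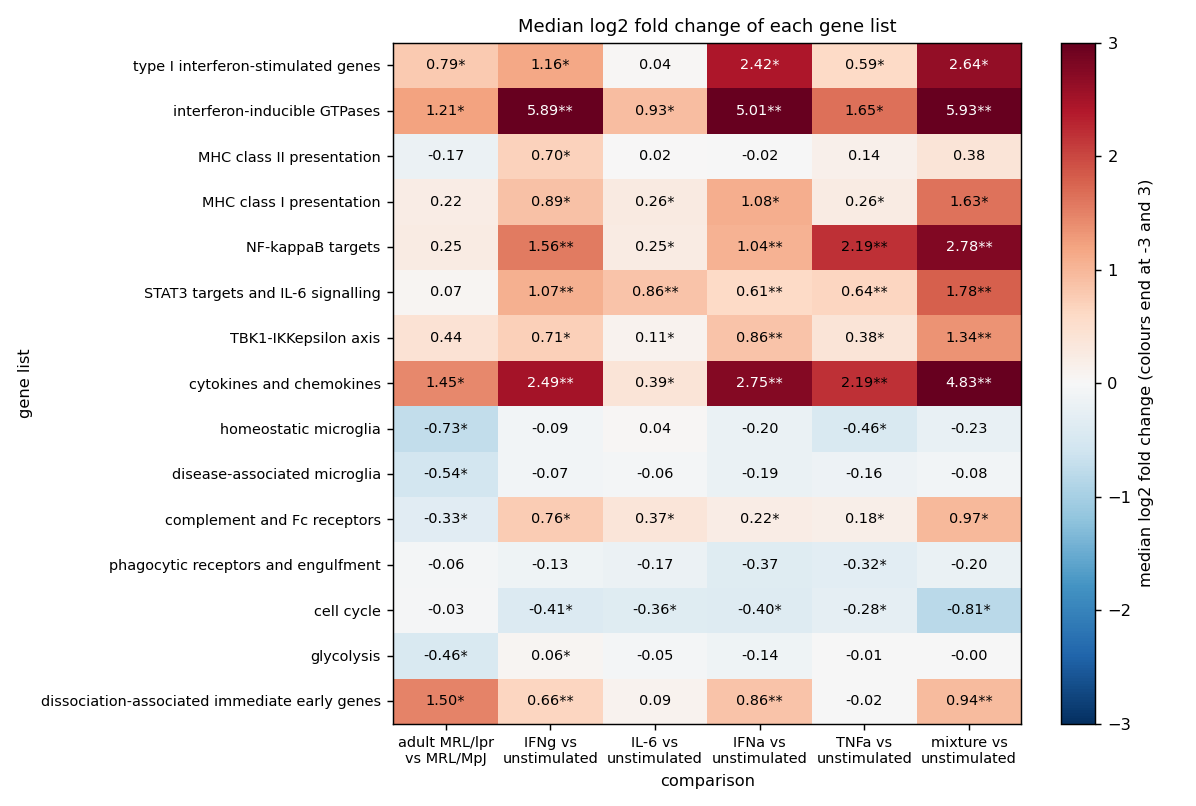
Median log2 fold change of the genes of each function list (vertical axis) in the adult comparison and the 5 cytokine comparisons (horizontal axis), as colours that end at -3 and 3. One asterisk marks a camera adjusted p under 0.05 and a double asterisk a call kept with an estimated correlation, as for NF-kappaB targets under IFNg, IFNa, TNFa and the mixture.

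The mixture was compared with each cytokine to ask what it adds to single cytokines. Against TNFa it added little Ikbke: 1.44-fold (0.53 ± 0.224, edgeR adjusted p = 0.101), which passed with the replicate block (0.0227), DESeq2 (0.0429) and limma-voom (0.0463). Ikbke was 6.46-fold higher with the mixture than with IFNg (2.69 ± 0.239, edgeR adjusted p = 5.87e-06), 12.9-fold higher than with IFNa (3.69 ± 0.251, 4.15e-07) and 17.7-fold higher than with IL-6 (4.15 ± 0.257, 3.18e-08). Over IFNg and IFNa the mixture added NF-kappaB targets and chemokines, and over TNFa it added Cxcl9.

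Against IFNg, NF-kappaB targets were higher with the mixture in 24 of 29 (25 adjusted over the list alone, camera adjusted p = 6.34e-22 and 0.00442 with an estimated correlation) and cytokines and chemokines in 17 of 30 (24 adjusted over the list alone, camera adjusted p = 2.53e-18 and 0.00442 with an estimated correlation). Interferon-stimulated genes of type I were higher in 21 of 30 (23 adjusted over the list alone, camera adjusted p = 3.18e-17 and 0.216 with an estimated correlation), and the GTPase list did not pass (camera adjusted p = 0.196). The TBK1-IKKepsilon axis (7.53e-05), MHC class I genes (6.23e-05), complement genes (camera adjusted p = 0.0228) and, downwards, cell cycle genes (0.027) passed and lost the call with an estimated correlation (adjusted p = 0.216 to 0.634), while immediate early genes kept it (0.00379 and 0.0296). Without IFNg replicate 1 the complement and cell cycle lists lost theirs (0.0742 and 0.209), as without mixture replicate 3 (0.136 and 0.3). The cell cycle list also lost it without mixture replicate 2 (0.0825) and with total counts (0.0688), and the monocyte list passed with total counts (0.0175). The largest differences were Nos2 (5.85 ± 0.746), Ccl5 (5.41 ± 0.456), Ifit1bl1 (4.82 ± 1.22), Traf1 (4.80 ± 0.495) and Cxcl11 (4.59 ± 0.834), and downwards the myeloid transcription factor gene Cebpa (-3.0 ± 0.359), Egr2 (-2.82 ± 0.606), Amz1 (-2.68 ± 0.353), Rab3il1 (-2.63 ± 0.432) and Zfp395 (-2.42 ± 0.461). Fas (2.00 ± 0.898, edgeR adjusted p = 0.17) did not pass, and passed with the replicate block (0.0337), DESeq2 (0.0298) and limma-voom (0.0101). The edgeR test called 2089 genes, 944 higher and 1145 lower. The replicate block called 3844, total counts 735 higher and 2769 lower, and RLE size factors 1141 higher and 886 lower. Without IFNg replicate 1 the count was 1333 and Ifit1bl1 lost its call (0.0774).

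Against IFNa, NF-kappaB targets were higher with the mixture in 26 of 29 (28 adjusted over the list alone, camera adjusted p = 3.12e-45 and 0.000335 with an estimated correlation), STAT3 targets in 9 with 1 lower of 20 (12 and 2 adjusted over the list alone, 5.23e-09 and 0.00222) and cytokines and chemokines in 14 of 30 (17 adjusted over the list alone, 9.12e-18 and 0.00222). Complement genes were higher in 6 of 21 (11 adjusted over the list alone, camera adjusted p = 9.98e-10 and 0.047 with an estimated correlation). Of the type I interferon-stimulated genes, 0 of 30 differed (median 0.36, camera adjusted p = 0.00505 and 0.548 with an estimated correlation). GTPases (5.65e-07), MHC class I (8.94e-06) and II genes (0.0114), the TBK1-IKKepsilon axis (0.000877), glycolytic (0.00644), immediate early (0.0337) and disease-associated genes (0.0343) passed upwards and cell cycle genes (camera adjusted p = 0.000117) downwards, and all of these lost the call with an estimated correlation (adjusted p = 0.115 to 0.378). The dendritic cell list passed with 1 of 4 genes called (0.00193 and 0.196 with an estimated correlation). It lost the call without IFNa replicate 1 (0.0741), mixture replicate 1 (0.173) or 3 (0.0849). Without IFNa replicate 1 or mixture replicate 3 the immediate early (0.0649 and 0.0724) and disease-associated lists (0.119 and 0.109) lost theirs, the last also without mixture replicate 2 (0.0526). With total counts the glycolytic (0.306), disease-associated (0.248) and immediate early lists (0.0552) lost theirs, and the homeostatic and monocyte lists passed (0.0274 and 0.0375). The homeostatic list also passed without IFNa replicate 1 (0.00946) or mixture replicate 3 (0.00596). Nos2 (5.97 ± 0.752), Cxcl11 (5.87 ± 0.889), Traf1 (5.70 ± 0.526), Cxcl9 (5.55 ± 0.798) and Ccl5 (5.1 ± 0.448) led upwards, and Cebpa (-3.31 ± 0.364), Baiap2l2 (-2.79 ± 0.624), Zfp395 (-2.63 ± 0.464), Asb10 (-2.48 ± 0.464) and Abcd2 (-2.32 ± 0.235) downwards. Fas was higher (4.86 ± 1.05, edgeR adjusted p = 0.00813). The edgeR test called 1161 genes, 608 higher and 553 lower, the replicate block 2689, and total counts 448 higher and 1939 lower. Without IFNa replicate 3 the count was 681, and without mixture replicate 3 Baiap2l2 lost its call (0.0585). Zfp395 fell by 1.95 without IFNa replicate 3.

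Against TNFa, GTPases were higher with the mixture in 17 of 17 (camera adjusted p = 5.18e-18 and 0.0952 with an estimated correlation), type I interferon-stimulated genes in 25 of 30 (26 adjusted over the list alone, 5.18e-18 and 0.142 with an estimated correlation) and cytokines and chemokines in 17 with 2 lower of 30 (17 and 3 adjusted over the list alone, 3.27e-09 and 0.0453 with an estimated correlation). Immediate early genes kept their call too (0.00012 and 0.0169). Complement genes (5.22e-05), MHC class I genes (1.5e-09), NF-kappaB targets (0.00012), the TBK1-IKKepsilon axis (0.000262) and STAT3 targets (0.00411) passed upwards and cell cycle genes (camera adjusted p = 0.00676) downwards, and lost the call with an estimated correlation (adjusted p = 0.105 to 0.425). The cell cycle list lost it without mixture replicate 3 (0.0811), and the endothelial list passed with total counts (0.0296). Cxcl9 (10.86 ± 1.04), Il12rb1 (8.93 ± 0.861), Serpina3g (8.68 ± 0.69), Iigp1 (8.07 ± 0.953) and Serpina3f (7.77 ± 0.586) led upwards. The largest falls were in Tmem119 (-4.64 ± 0.418), Gpr183 (-3.99 ± 0.616), H2-M2 (-3.54 ± 0.596), Mturn (-3.51 ± 0.437) and Treml4 (-3.40 ± 0.777). Fas (1.67 ± 0.885, edgeR adjusted p = 0.203) did not pass, and passed with the replicate block (0.0447) and limma-voom (0.00779). The edgeR test called 3684 genes, 1839 higher and 1845 lower, and with total counts 1332 were higher and 4184 lower.

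Against IL-6, type I interferon-stimulated genes were higher with the mixture in 27 of 30 (camera adjusted p = 6.17e-20 and 0.133 with an estimated correlation), NF-kappaB targets in 26 of 29 (7.38e-26 and 0.0029), and cytokines and chemokines in 26 of 30 (27 adjusted over the list alone, 1.57e-18 and 0.0029). Immediate early genes kept their call too (0.000695 and 0.0134). GTPases (7.15e-18), MHC class I genes (2.05e-09), the TBK1-IKKepsilon axis (2.3e-07), complement genes (0.000695) and STAT3 targets (0.0193) passed upwards and cell cycle (0.0104) and homeostatic genes (camera adjusted p = 0.0172) downwards, and lost the call with an estimated correlation (adjusted p = 0.0647 to 0.411). The cell cycle list lost it without IL-6 replicate 1 (0.0539) or mixture replicate 3 (0.0799). With total counts the monocyte, dendritic cell and endothelial lists passed (camera adjusted p = 0.016, 0.016 and 0.0369). Without 1 library the dendritic cell list passed in 3 fits (0.0305 to 0.0426) and the neuron list in 2 (0.0311 and 0.0418). Cxcl11 (10.68 ± 1.15), Nos2 (10.61 ± 1.05), Cxcl10 (10.52 ± 0.969), Cxcl9 (9.34 ± 0.964) and the itaconate-forming enzyme gene Acod1 (9.31 ± 0.669) led upwards. The largest falls were in Rtn4rl1 (-4.90 ± 0.546), Rab3il1 (-4.67 ± 0.469), Gpr183 (-4.57 ± 0.627), Sema6b (-3.89 ± 0.344) and Cebpa (-3.66 ± 0.37). Fas was higher (4.28 ± 1.01, edgeR adjusted p = 0.00401). The edgeR test called 4106 genes, 2018 higher and 2088 lower, and with total counts 1401 were higher and 4628 lower.

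IFNg and IFNa were compared to separate both interferon types. Ikbke was 2.00-fold higher with IFNg (1.00 ± 0.231, edgeR adjusted p = 0.0181), a call lost without any of 5 of the 6 libraries (up to 0.0837 without IFNa replicate 1). Higher with IFNg were Cdc42ep2 (4.47 ± 0.493), Socs3 (4.06 ± 0.543), Egr2 (3.61 ± 0.632), Cxcl9 (3.56 ± 0.728) and the feedback inhibitor Socs1 (3.52 ± 0.602). Higher with IFNa, and so negative here, were Ifit1bl1 (-5.38 ± 1.25), Ifit3b (-3.77 ± 0.854), Rilpl1 (-3.56 ± 0.407), Cmpk2 (-3.51 ± 0.792) and Rsad2 (-3.34 ± 0.873). Interferon-stimulated genes of type I were lower with IFNg in 10 of 30 (17 adjusted over the list alone, median -0.93, camera adjusted p = 3.59e-16 and 0.204 with an estimated correlation). Higher with IFNg were NF-kappaB targets in 10 of 29 (13 adjusted over the list alone, camera adjusted p = 6.71e-10 and 0.0794 with an estimated correlation), STAT3 targets in 8 of 20 (8 and 1 lower adjusted over the list alone, 0.000123 and 0.0683 with an estimated correlation) and MHC class II genes in 2 of 12 (3 adjusted over the list alone, 0.00138 and 0.0861 with an estimated correlation). GTPases (0.000153), complement genes (0.000139) and glycolytic genes (camera adjusted p = 0.00166) also passed and lost the call with an estimated correlation (adjusted p = 0.141 to 0.451). Without IFNa replicate 3 the cytokine (0.00647) and phagocytic lists (0.0456) passed, and without IFNg replicate 1 the cell cycle list (0.0238). Fas (2.86 ± 0.986, edgeR adjusted p = 0.126) did not pass, and passed with the replicate block (0.00673) and DESeq2 (0.0133). The edgeR test called 756 genes, 411 higher and 345 lower, and the replicate block 2058. Without IFNg replicate 2 the count was 325, and Ifit1bl1 (edgeR adjusted p = 0.115), Ifit3b (0.11), Cmpk2 (0.0995) and Rsad2 (0.176) lost their call.

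The mixture was also set against the sum of the 4 single log2 changes, to ask whether cytokine folds multiply. Sums of levels were not tested. Ikbke fell short of that sum (log2 difference -4.62 ± 0.667, edgeR adjusted p = 0.00178), and Fas did not differ from it in the test (2.60 ± 2.37, edgeR adjusted p = 0.829). Falling furthest short were Acod1 (-14.10 ± 1.68), Cxcl10 (-13.45 ± 2.31), Iigp1 (-13.37 ± 2.83), Cd69 (-11.86 ± 1.9) and Ccl12 (-11.78 ± 1.64). Above the sum were Cd28 (5.66 ± 0.916), S1pr1 (5.33 ± 0.877), Gpr34 (5.1 ± 0.673), St6gal1 (4.96 ± 0.61) and Slc46a3 (4.92 ± 0.506). GTPases fell short in 5 of 17 (15 adjusted over the list alone, median -7.83, camera adjusted p = 8.32e-26 and 0.0272 with an estimated correlation), NF-kappaB targets in 12 of 29 (15 adjusted over the list alone, 2.04e-21 and 0.00515), STAT3 targets in 7 of 20 (11 adjusted over the list alone, 2.46e-13 and 0.000668) and cytokines and chemokines in 3 of 30 (10 adjusted over the list alone, 1e-08 and 0.0272). Interferon-stimulated genes of type I (camera adjusted p = 1.58e-05), MHC class I genes (2.29e-05), the TBK1-IKKepsilon axis (2.36e-06) and complement genes (0.00754) were below the sum and cell cycle (0.000792), phagocytic (0.00707) and homeostatic genes (0.0349) above it, and all lost the call with an estimated correlation (adjusted p = 0.0934 to 0.403). Without unstimulated replicate 1 the interferon-stimulated, cell cycle and complement lists lost theirs (0.0572, 0.0572 and 0.0695), and without unstimulated replicate 3 the phagocytic list (0.249). The homeostatic list lost its call without any 1 of 9 libraries (0.0505 to 0.346). No marker list passed with all libraries (camera adjusted p from 0.666 to 0.985), but the T cell list passed without any 1 of 16 of the 18 libraries (0.00464 to 0.0408) and the neutrophil list without unstimulated replicate 3 (0.00124). Disease-associated genes did not pass (camera adjusted p = 0.115) and passed with the replicate block (0.0243), with total counts (0.0427) and without unstimulated replicate 1 (0.00433). The edgeR test called 245 genes, 78 above and 167 below the sum, and 960 with the replicate block, 323 above and 637 below. Without unstimulated replicate 1, 2 or 3 the count was 113, 76 or 126, and without unstimulated replicate 2 Cxcl10 (edgeR adjusted p = 0.0764) and Iigp1 (0.177) lost their call and Acod1 fell short by 12.87, Cd69 by 10.79 and Ccl12 by 10.87. With limma-voom Cxcl10 (adjusted p = 0.218), Iigp1 (0.466), Cd69 (0.306) and Ccl12 (0.169) lost it. The sum of changes takes the unstimulated libraries 4 times, so it rests on them more than a single comparison does.

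The adult difference was compared with each cytokine response, which shares no library with it, to ask whether adult MRL/lpr microglia hold a cytokine signature. Of the 567 genes that rose in adult MRL/lpr and with the mixture, the 10 largest by the smaller of both changes were Gbp4, Gbp6, Cxcl9, Iigp1, Nlrc5, Slfn4, Mx1, Tgtp2, Ikbke and Ly6i. Of 12781 genes tested in both, 373 rose in adult MRL/lpr and with IFNa, against 301.5 if the lists were independent (odds ratio 1.38, Fisher's exact test two-sided, adjusted p = 2.32e-06 over 10 tests). The shared rises were 334 against 278.4 with IFNg (odds ratio 1.31, exact adjusted p = 0.000126), 567 against 495.5 with the mixture (1.24, 0.000123), 166 against 143.2 with TNFa (1.23, 0.0346) and 26 against 23.78 with IL-6 (1.13, 0.638). Shared falls were 212 against 143.3 with IFNg (1.78, exact adjusted p = 1.3e-09), 240 against 167.6 with IFNa (1.7, 1.35e-09), 185 against 122.5 with TNFa (1.83, 1.35e-09), 656 against 544 with the mixture (1.37, 6.28e-09) and 11 against 7.57 with IL-6 (1.68, 0.168). Genes raised by a cytokine but lower in adults were 283 against 273.8 with IFNg, 266 against 296.5 with IFNa, 490 against 487.3 with the mixture, 155 against 140.8 with TNFa and 32 against 23.39 with IL-6. Genes lowered but higher in adults were 122 against 145.7, 167 against 170.4, 545 against 553.1, 89 against 124.5 and 11 against 7.69. Genes are not independent replicates in this test.

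**Figure D4:**
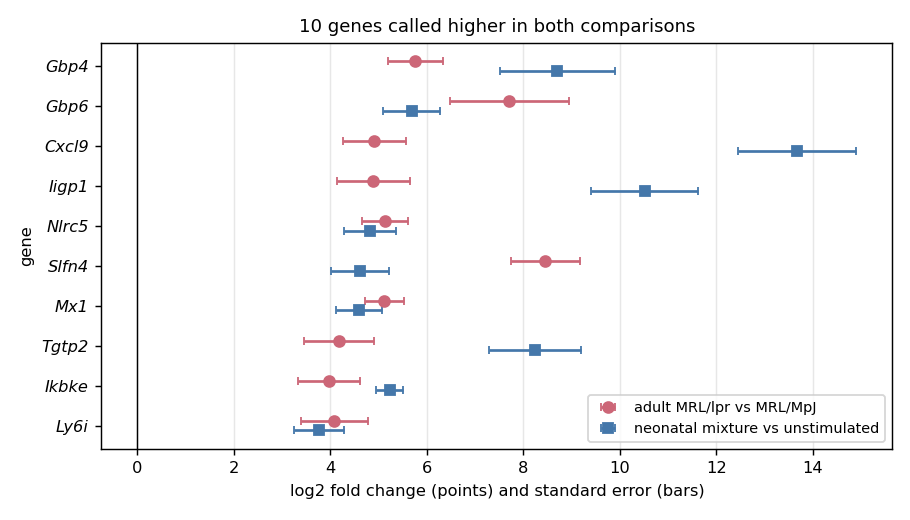
Log2 fold change (horizontal axis, with bars for the standard error) of 10 genes called higher in adult MRL/lpr against MRL/MpJ microglia (circles) and in neonatal cells with the mixture against unstimulated cells (squares). Gbp6 had 0 reads in MRL/MpJ, so its adult circle depends on the prior count, and its fold is at least 21.9.

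As whole lists, the genes raised by each cytokine did not stand apart in the adult comparison: IFNg (1194 genes, 334 higher and 283 lower, median 0.05, camera adjusted p = 0.766), IFNa (1293 genes, 0.10, 0.438), TNFa (614 genes, 0.02 with the test pointing down, 0.792), the mixture (2125 genes, 0.04, 0.766) and IL-6 (102 genes, -0.10, 0.617). Against no change (fry), those raised by IFNg, IFNa and the mixture moved up (fry adjusted p = 0.0422, 0.0354 and 0.0354) and those lowered by TNFa down (0.0354). The 100 genes raised most by IFNg, IFNa and the mixture passed (camera adjusted p = 0.000134, 9.21e-05 and 5.19e-05) and lost the call with an estimated correlation (adjusted p = 0.331 for each). Genes lowered by TNFa were lower in adult MRL/lpr (534 genes, 89 higher and 185 lower, median -0.22, camera adjusted p = 0.00804 and 0.878 with an estimated correlation), as were genes lowered by IFNg (625 genes, 122 higher and 212 lower, median -0.14, camera adjusted p = 0.0263 and 0.878 with an estimated correlation). Both lost their call with total counts (0.079 and 0.149), and the IFNg list also without MRL/lpr replicate 2 (0.292). Genes lowered by IFNa (731 genes, median -0.10, camera adjusted p = 0.169; 0.0296 without MRL/MpJ replicate 2), the mixture (2372 genes, -0.05, 0.423) and IL-6 (33 genes, 0.617) did not pass. Neither did genes higher with IFNg than with IFNa (399 genes, 0.47) or higher with IFNa than with IFNg (337 genes, 0.707).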

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

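The fits without 1 replicate number in every neonatal group at once, the removal of the intron trend in adults, and the estimated correlation for the 100 most changed genes were chosen after seeing the data. No named fold change turned its direction under any alternative. The 12 counts of called genes stayed within 1.5 times with limma-voom, RLE size factors, no filter and the stricter filter. Of 326 list tests, 88 lost their call with an estimated correlation, and fry ended 28 and added 28. For the genes of the naming rule, no filter ended 20 calls, limma-voom 18, only the groups compared 16, total counts 5 and, in adults, all 24 libraries in 1 fit 3. Without 1 library the folds of 21 called names shrank and of 80 grew by over 1.5 times, 41 of these without unstimulated replicate 3. Apart from the calls given with each comparison, the replicate block changed no call of a named gene or list in the neonatal libraries. In the adult comparison, whose numbers do not pair (2 of 3 pairs over 0.1), it called 6921 genes, ended the call of Itga4 and passed the TBK1-IKKepsilon axis (camera adjusted p = 0.0478). With the intron trend removed in adults, NF-kappaB targets (0.0473) and phagocytic receptors (0.0162) passed and the oligodendrocyte list (0.061) did not. Cenpe (edgeR adjusted p = 0.221) and Itga4 (0.0581) lost their call, monocyte markers rose in 2 in place of 5, and homeostatic genes in 3 in place of 0. The causes of these changes were not tested. Fits without libraries hold fewer samples and, without 1 neonatal library, replicate numbers that are unbalanced and not modelled. Where a group was left with 2 libraries, its spread was taken from the pooled fit.

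With the replicate block the counts were 3468 for IFNg, 714 for IL-6, 3712 for IFNa, 2542 for TNFa, 3844 for the mixture against IFNg, 2689 against IFNa, 2058 for IFNg against IFNa and 960 for the mixture against the sum of singles. DESeq2 called 373 genes for IL-6, 1750 for the mixture against IFNa, 1193 for IFNg against IFNa and 512 against the sum. With total counts the mixture differed from IFNg in 3504 genes and from IFNa in 2387. With only the groups compared, IL-6 changed 85 genes and the mixture differed from IFNa in 423. For the sum this fit is that of all neonatal libraries.

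Without libraries, counts were 4733 to 6519 in adults, 574 to 1815 for IFNg, 14 to 172 for IL-6, 549 to 2267 for IFNa, 403 to 1006 for TNFa and 2838 to 4406 for the mixture. For the mixture they were 520 to 1962 against IFNg, 2388 to 3827 against IL-6, 383 to 1115 against IFNa, 1984 to 3383 against TNFa and 0 to 338 against the sum, and for IFNg against IFNa 68 to 1036. Without 1 library, higher or lower counts moved over 1.5 times in all neonatal comparisons but the mixture against unstimulated cells, IL-6 and TNFa. The 0 came from edgeR without replicate 2, with 884 genes at an unadjusted p under 0.05, and no other tool was run without those libraries. The type I interferon list under IL-6 gave camera adjusted p from 0.00135 to 0.575 without 1 library, in both directions.

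In the adult comparison, genes lowered by IFNg had a camera adjusted p of 0.878 with an estimated correlation, 0.149 with total counts and 0.00293 to 0.292 without 1 library. Genes lowered by TNFa had 0.878 with an estimated correlation and 0.079 with total counts, and genes lowered by IFNa 0.0296 to 0.65 without 1 library. The 100 genes raised most gave 0.000134 for IFNg, 9.21e-05 for IFNa and 5.19e-05 for the mixture, and 0.331 for each with an estimated correlation. The 100 lowered most gave 0.331 for IFNg and 0.356 for TNFa with it. At depths of 10.08 to 19.32 M counts per library, the low CPM of Fas rests on few reads.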

Other observations

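Of the tests in this part, the splits, and the removal of the intron trend from the interferon and glucocorticoid lists, were planned before their result was seen, and all others, with both contrasts of the first paragraph, were chosen after.

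Among the homeostatic genes, P2ry12, P2ry13, Sall1 and Tmem119 moved in opposite directions with each interferon and with TNFa, while Gpr34 fell with all of them. With IFNg, the purinergic receptor genes P2ry13 (log2 difference 3.51 ± 0.4, edgeR adjusted p = 2.53e-05) and P2ry12 (2.67 ± 0.261) and the transcription factor gene Sall1 (1.32 ± 0.148) were higher than with TNFa. Tmem119 (-3.74 ± 0.394) and Cx3cr1 (-2.76 ± 0.314) were lower. With IFNa against TNFa, P2ry13 differed by 3.28 ± 0.397 and Tmem119 by -3.30 ± 0.385. Of the 20 homeostatic genes, 6 were higher and 3 lower with IFNg, and 6 higher and 4 lower with IFNa. With the replicate block these were 6 and 5, and 6 and 6.

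Adult MRL/lpr libraries held more nuclear and intron-rich transcripts, with Firre (5.11 ± 0.246) and Malat1 (3.11 ± 0.321) higher. Genes with a retained-intron transcript stood 0.515 (95% interval 0.331 to 0.608) in log2 above single-exon genes, consistent with more nuclear or incompletely spliced RNA. Genomic DNA would raise single-exon genes. The 216 expressed ones stood lower (log2 difference -0.425, -0.516 to -0.24), but could miss a low DNA background. Length and GC content alone leave the contrast at 0.45 (0.292 to 0.539), which argues against them as the whole cause. Chemosensory receptor reads were 3.09 times as many in MRL/lpr (12.4 ± 2.03 against 4.01 ± 0.393 plain CPM), so genomic DNA stays open. Batch cannot be told apart from strain, and a strain difference was not tested.

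Interferon-stimulated genes, chemokines and Ikbke were higher in adult MRL/lpr. After removal of the intron trend the interferon list kept a median of 0.77 (0.623 to 1.251) and Ikbke a log2 change of 3.80 ± 0.613, which argues against that shift as the cause. Lymphocytes in the preparations cannot be told apart as a source, since 15 T and NK cell markers were called higher, Gzma at 27.6 ± 3.66 and Prf1 at 13.2 ± 1.52 CPM in MRL/lpr. CD11b selection would remove most T cells but not NK cells, which carry CD11b. Interferon in the diseased brain stays open and was not tested.

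Ddit4 (-3.23 ± 0.56) and Tsc22d3 (-2.30 ± 0.313), both induced by glucocorticoids, were lower in adult MRL/lpr. The 18 other genes of a glucocorticoid-induced list had a median of -0.241 (2 rose and 5 fell), and -0.146 (-0.318 to 0.075) after removal of the intron trend. Its camera test did not pass (camera adjusted p = 0.234 over 1 test). A lower glucocorticoid response and the intron shift cannot be told apart, since the interval includes 0 and members go both ways.

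For each of the 11 comparisons of 3 against 3 libraries, 1 of the 10 splits, the real one, gave as many called genes, and the highest other gave 0. With 10 splits the share cannot fall under 0.05. The real counts, from 143 for IL-6 to 6310 in adults, are given with each comparison. For the mixture against the sum of singles, 2 of 100 regroupings of the 18 neonatal libraries, the real one with 245 genes included, gave as many. The share does not settle chance, since random regroupings mix treatments within groups and do not keep replicate numbers apart as the real groups do. The other gave 324 and had kept the 3 mixture libraries together as 1 group.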
